A study of Chlamydomonas reinhardtii and Caenorhabditis elegans with 28 samples.

How the data were processed

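The data are 28 libraries in 14 groups of 2. RNA-seq and Ribo-seq of Chlamydomonas reinhardtii CC-125 cover non-treated cells and 4 later times (15, 30, 60 and 90 min). Time runs from deflagellation, the shock that makes the alga shed its flagella and grow new ones. Per the labels, footprints were made by RNase I digestion, the RNA-seq libraries followed the same strategy as the Ribo-seq libraries, and the reference was taken from the same culture before deflagellation. RNA-seq of whole Caenorhabditis elegans covers the strains RB1465, VC2358, RB1579 and N2, with Trizol extraction and the KAPA RNA HyperPrep kit per the labels' protocols. The stage of the worms is not given in the sources used here. Groups and replicate numbers were taken from the sample titles. The deposited tables of the 2 sptl-3 libraries carry other replicate numbers than the titles, and each table was assigned to the sample it is recorded under.

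The deposited values are whole-number read counts per gene, not normalised. Per the submitters' processing notes, TopHat2 2.1.1, TopHat, HTSeq and deepTools were used for the alga, and FastQC, Bowtie, STAR 2.6.1c, HTSeq, DESeq2 and deepTools with the build WBcel235 for the worm. Per the names the authors gave their tables, RNA counts are over exons, and footprint counts over coding sequences. Whether counting used strand is not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies such as histone genes, can be divided between genes. The RNA-seq counts of the alga cover 13172 genes, its Ribo-seq counts 17741 and the worm counts 46758. The authors' CPM tables (counts scaled to the library total, with edgeR named by the authors) hold 17741 genes for RNA-seq and 14399 for Ribo-seq. They served only as a check: for the genes in both tables the counts divided by the CPM column's total gave the same values. A further 14 sample columns in 3 deposited tables of normalised worm values were not used, because the raw counts of each worm library were at hand and some of these columns match no sample.

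Identifiers were looked up in the reference tables. Of the RNA-seq IDs 13170 matched, of the Ribo-seq IDs 17738 and of the worm IDs 43798, of which 11179 have a gene-class symbol. The reference of the alga (Chlamydomonas_reinhardtii_v5.5) gave no symbols, so its 18 fixed gene lists could not be matched and its genes appear by ID only. In the worm 27 symbols are given to more than 1 tested ID (55 IDs in all).

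Genes with enough counts were kept with filterByExpr, which left 2707 genes for RNA-seq, 8343 for Ribo-seq, 2629 for translational efficiency and 18910 for the worm. Counts were scaled by TMM (factors 0.640 to 1.90 for RNA-seq, 0.889 to 1.38 for Ribo-seq and 0.843 to 1.19 for the worm) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, 1 model per assay over all its groups, with p-values adjusted by Benjamini-Hochberg and a threshold of 0.05. Translational efficiency was the interaction of assay and time in 1 model over the 20 libraries of the alga, with TMM within each assay. Standard errors are the absolute log2 fold change divided by the square root of the F statistic, and CPM values are TMM-scaled. With 2 libraries per group, each p-value rests on a spread shared by all groups of the assay. Where a group had 0 counts, the fold is a bound against 3 counts over the group. Bounds and depths cover counting error only, since the reads carry no molecular identifiers.

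The comparisons, tests, gene lists, naming rule and alternatives were set before the data were examined. For each worm mutant the text draws its genes from the 8 rising and 8 falling genes with symbols and the largest changes among called genes of at least 5 CPM whose libraries do not overlap between the groups, up to 3 called members of each list, and the sptl genes throughout. These rules gave 54 genes for sptl-1, 64 for sptl-2 and 70 for sptl-3. The naming rule could not be used for the alga, where 4 IDs stand for the largest changes in footprints. Lists with 5 or more tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the 114 tests of 19 lists in 6 worm comparisons. Of the 57 tests against wild type 29 passed with the preset correlation, and 24 of these also with fry. Fry tests whether a list moves on balance in 1 direction without comparing it with other genes. With an estimated correlation 0 of the 114 tests passed, and the lowest adjusted p was 0.219. Even the ribosomal protein list in sptl-3, with 79 of 81 genes lower, stood at 0.271. Failing that alternative therefore does not tell lists apart. Alternatives were RLE factors, library totals (summed over the tested genes, which for translational efficiency hold 1 of the 2 most abundant RNA-seq genes), no filter, DESeq2 1.42.0, a replicate block, a fit on the compared groups alone, leaving out each library, limma on log2 ratios of CPM with a pseudocount of 1 for translational efficiency, and a 2-fold minimum for overlaps. Correlations and covariances between comparisons were set beside simulations of unchanged groups that share their controls, 40 for the alga and 30 for the worm.

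The pipeline was tested on simulated counts with 200 changed genes at the depth of the real libraries. Changes of 2-fold and 4-fold were recovered for 10% and 63% of genes in the RNA-seq at 30 min (2707 genes), 25% and 72% in the Ribo-seq (8343 genes), 8% and 47% for translational efficiency (2629 genes) and 40% and 82% in sptl-1 against wild type (18910 genes). False calls made up 3.95%, 4.90%, 1.79% and 8.27% of all calls. Of the simulated lists, 1 of 1 changed and 0 of 19 unchanged lists were called. Each library was counted as a replicate because the labels call the libraries of a group biological duplicates. They differed by more than sampling noise, with chi-square per degree of freedom from 1.42 in the RNA-seq of non-treated cells to 8.69 in sptl-2, which does not separate biological from technical variation.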

Results

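The series joins a time course of flagellar regeneration in the green alga Chlamydomonas reinhardtii with worms of knockout strains for the subunit genes of serine palmitoyltransferase, the enzyme that makes the first committed intermediate of sphingolipids. Cells of the wild-type strain CC-125 were sampled before deflagellation (non-treated) and 15, 30, 60 and 90 min after it, each time by RNA-seq and by Ribo-seq, which sequences the RNA fragments that ribosomes protect from RNase I. The worms (Caenorhabditis elegans) were the knockout strains RB1465 (sptl-1), VC2358 (sptl-2) and RB1579 (sptl-3) and the wild type N2, measured by RNA-seq. Each of the 14 groups held 2 libraries, which the labels call biological duplicates. Total counts ran from 429238 to 930386 per RNA-seq library of the alga, from 179494 to 873359 per Ribo-seq library, and from 3221645 to 20734380 per worm library. The sptl-3 libraries were the shallowest worm libraries (3221645 and 3334358 counts) and the sptl-1 libraries the deepest (13155709 and 20734380). In the RNA-seq of the alga a single gene took 64.3% to 78.2% of the counts and the next 10.4% to 12.8%, which left 71006 to 167990 counts for all other genes.

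Ribosome footprints changed on many genes of the alga within 15 min of deflagellation, and large changes were still present at 90 min. Against non-treated cells, footprints rose on 1673 genes and fell on 1504 at 15 min, of 8343 genes tested. They rose on 2024 and fell on 1711 at 30 min, rose on 1574 and fell on 1599 at 60 min, and rose on 1620 and fell on 1997 at 90 min (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). Most of these changes reached 2-fold, with 1752 genes higher and 1536 lower by that much at 30 min, and the median log2 change of the called genes at that time was 1.71 for rises and −1.85 for falls. Of the genes called, 459 were higher at some time and lower at another. The gene Cre11.g467599.v5.5 had 0 counts in non-treated cells and 107.4 ± 45.4 CPM (SD, n = 2) at 30 min, at least 22.5-fold higher against a floor of 3 counts over the group, or 4.78 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.4e-07). Cre12.g546500.v5.5 likewise went from 0 counts to 63.2 ± 27.4 CPM (SD, n = 2) at 90 min, at least 13.2-fold higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.6e-06). In the other direction, Cre09.g391650.v5.5 went from 296 ± 6.63 CPM (SD, n = 2) to 0 counts at 60 min, at least 52.4-fold lower against a floor of 5.65 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.3e-13). Cre03.g162800.v5.5 went from 261 ± 5.68 CPM (SD, n = 2) to 0 counts at the same time, at least 46.1-fold lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.5e-11). The balance of rises and falls depended on the scaling: with library totals alone, the median of all genes moved to −0.55, −0.59, −0.74 and −0.76 at 15, 30, 60 and 90 min. The calls became 1156 higher and 2747 lower, 1240 and 3022, 984 and 2996, and 957 and 3428. The total of calls fell by more than 1.5 times without non-treated replicate 1 at 15 min (2088), 60 min (2096) and 90 min (2242), without 60 min replicate 2 at 60 min (1893), and with DESeq2 at 15 min (2110), 60 min (2088) and 90 min (2384). The falls changed more than the rises: they numbered 819, 1053, 951 and 1134 without non-treated replicate 1, 823, 1136, 902 and 1249 with DESeq2, 804 without 15 min replicate 2, 732 without 60 min replicate 2 and 1222 without 90 min replicate 2.

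**Figure D1:**
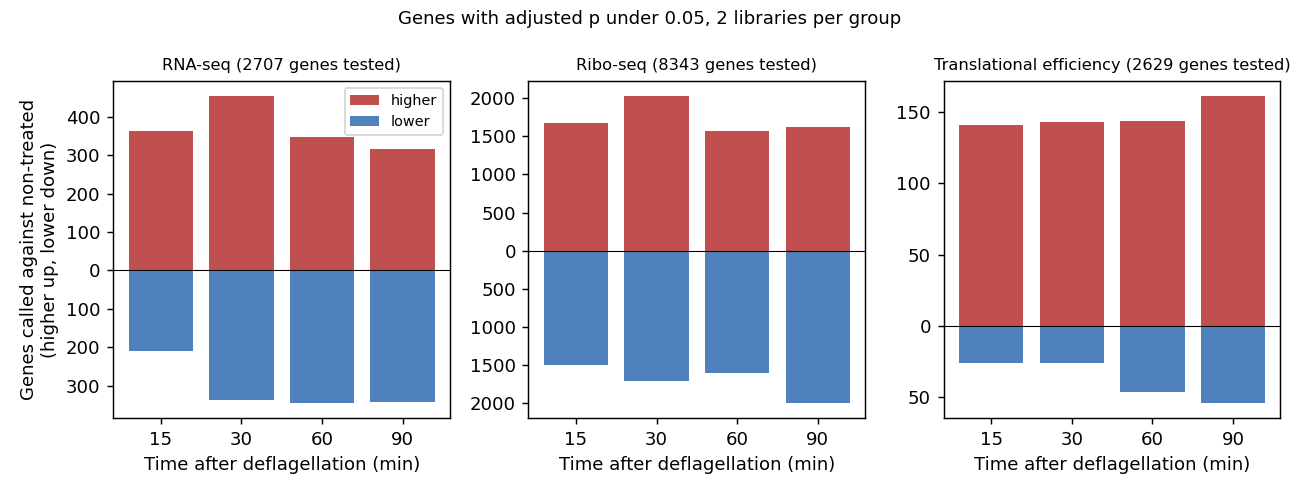
Number of genes called higher (up) and lower (down) than in non-treated cells at each time in minutes after deflagellation, for RNA-seq, Ribo-seq and their ratio, translational efficiency (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05, 2 libraries per group). At 30 min the bars stand at 453 and 337 for RNA-seq, 2024 and 1711 for Ribo-seq, and 143 and 26 for translational efficiency; with library totals as the only scaling these become 826 in total with 700 higher, 1240 and 3022, and 108 and 279.

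Transcript levels of the alga changed over the same times. RNA rose for 363 genes and fell for 210 at 15 min, rose for 453 and fell for 337 at 30 min, changed for 693 at 60 min, rising for 348 of them, and rose for 317 and fell for 342 at 90 min, of 2707 genes with enough counts to be tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). At 30 min 443 of the rises and 301 of the falls reached 2-fold, and the median log2 change of the called genes was 2.55 for rises and −2.03 for falls. At different times 33 genes were called in both directions. With library totals alone the median of all genes moved to 0.42, 0.65, 0.95 and 1.20 at 15, 30, 60 and 90 min. The calls became 441 higher and 92 lower at 15 min, 700 higher of 826 at 30 min, 849 higher and 74 lower at 60 min, and 1099 and 57 at 90 min. Totals that left out the 2 most abundant genes, a scaling added after the data were seen, gave 442 higher and 240 lower at 60 min and 458 and 230 at 90 min. Without a filter on low counts the calls were 396 and 136, 515 and 242, 430 and 190, and 392 and 214 at 15, 30, 60 and 90 min. DESeq2 made 295, 429, 393 and 376 calls, with 192 higher and 184 lower at 90 min, and without non-treated replicate 2 the calls numbered 341, 518, 419 and 404, of which 99, 189, 155 and 183 were falls. The falls numbered 111, 210 and 190 at 15, 30 and 60 min without non-treated replicate 1. Without a library of the time itself they were 103 and 122 at 15 min (replicates 1 and 2), 217 at 30 min (replicate 1) and 211 at 90 min (replicate 1). Simulated changes of 2-fold were recovered for 10% of genes at this depth, so genes without a call were not shown to be unchanged.

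Many genes that had risen by 30 min were lower again at 90 min. Between 30 and 90 min, footprints rose on 1555 genes and fell on 1844, and RNA rose for 267 genes and fell for 537 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). Of the genes with more footprints at 30 min than in non-treated cells, 1058 had fewer at 90 min than at 30 min, where independent lists would share 447, and 515 went the other way, down and then up (319 for independent lists). For RNA these numbers were 292 and 73, where independent lists would share 89.9 and 33.2. The comparisons share the 30 min libraries, which by itself gives opposite changes. The Pearson correlation of the log2 changes across genes was −0.531 for footprints and −0.576 for RNA, close to the −0.496 and −0.487 of 40 simulations of unchanged groups. The covariances were −1.22 and −1.67, against −0.102 and −0.177 simulated. Genes called at 15 min were largely called at 30 min too: footprints on 1316 genes were higher and on 1086 lower at both times (406 and 308 for independent lists), and RNA of 240 genes was higher and of 159 lower (60.7 and 26.1). Across genes the log2 changes at these times had a Pearson correlation of 0.80 for footprints and of 0.80 for RNA (0.587 and 0.588 simulated). The covariances were 1.91 and 2.35, against 0.140 and 0.2496 simulated for unchanged groups that share their reference. Part of the excess may come from the shared non-treated libraries. With library totals alone the RNA calls between 30 and 90 min became 688 higher and 290 lower with the median of all genes at 0.71. With totals that left out the 2 most abundant genes they were 392 and 451. They were 187 and 338 without 90 min replicate 1, and 103 and 351 with DESeq2, which called 875 rises and 1315 falls in the footprints. Without 30 min replicate 1 or 2 the rises alone were 167 and 153 for RNA and 980 and 1027 for footprints.

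RNA and footprints of the same genes moved together. Across 2629 genes tested in both assays, the Pearson correlation of the log2 changes was 0.66, 0.74, 0.69 and 0.68 at 15, 30, 60 and 90 min, and the Spearman correlation 0.65, 0.71, 0.70 and 0.71. These are correlations across genes, which are not independent replicates. Both assays called 340, 431, 331 and 289 genes higher at the 4 times, where independent lists would share 140, 213, 133 and 113. Both called 142, 220, 228 and 255 genes lower, where independent lists would share 28.1, 47.4, 65.8 and 87.0. Opposite calls were made for 14, 26, 25 and 23 genes.

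Translational efficiency, the ratio of footprints to RNA, changed on far fewer genes and mostly upward. It rose for 141 genes and fell for 26 at 15 min, rose for 143 and fell for 26 at 30 min, rose for 144 and fell for 46 at 60 min, and rose for 161 and fell for 54 at 90 min, of 2629 tested in 1 model over both assays (edgeR quasi-likelihood interaction term, Benjamini-Hochberg adjusted p below 0.05). At 30 min the median log2 change of the called genes was 2.42 for rises and −2.18 for falls. The median over all tested genes lay below 0, at −0.30, −0.29, −0.41 and −0.46, and library totals alone moved it to −0.71, −0.90, −1.30 and −1.48. The balance depended on the scaling: with library totals the calls were 117 higher and 140 lower at 15 min, 108 and 279 at 30 min, 724 lower of 831 at 60 min, and 113 higher and 1122 lower at 90 min. With totals that left out the 2 most abundant RNA-seq genes they were 125 and 63, 129 and 103, 121 and 310, and 129 and 511. Ratios tested with limma gave 102, 84, 124 and 121 calls. The falls were few and unsteady, at 7, 10, 15 and 19 without RNA-seq non-treated replicate 1, 13, 6, 12 and 19 without replicate 2, 3, 6, 9 and 16 without a filter, and 51, 40, 69 and 33 in fits on the compared groups alone. Simulated changes of 4-fold were recovered for 47% of genes in this comparison and changes of 2-fold for 8%.

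In the worms, the sptl-1 and sptl-3 genes fell in the strains that carry their deletions, while the sptl-2 gene stood at 29.6 CPM both in its own strain and in the sptl-3 mutant. None of the 3 genes was absent from its own strain. The sptl-1 gene (WBGene00016020) had 87.9 ± 7.12 CPM in wild type and 26.0 ± 7.02 in the sptl-1 mutant (SD, n = 2), a log2 change of −1.75 (SE 0.19, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.4e-05). The sptl-3 gene (WBGene00011932) had 94.3 ± 9.36 CPM in wild type and 54.4 ± 5.61 in the sptl-3 mutant (SD, n = 2), a log2 change of −0.79 (SE 0.14, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000997). The sptl-2 gene (WBGene00018398) had 43.8 ± 8.23 CPM in wild type and 29.6 ± 1.16 in the sptl-2 mutant (SD, n = 2), a log2 change of −0.57 (SE 0.18, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0434). The level of this gene was 29.6 ± 3.09 CPM in the sptl-3 mutant and 33.4 ± 5.52 in the sptl-1 mutant (SD, n = 2), so its own strain did not stand apart from the other mutants. Its call in the sptl-2 mutant was lost without any 1 of the 4 libraries, with log2 changes of −0.31 without wild-type replicate 1, −0.75 without wild-type replicate 2, −0.59 without sptl-2 replicate 1 and −0.48 without sptl-2 replicate 2. It was also lost with RLE factors (−0.53), library totals (−0.29), DESeq2 (−0.53), the compared groups alone (−0.48) and thinned libraries (−0.46). In the sptl-3 mutant the other two subunit genes also fell, sptl-1 by 0.54 and sptl-2 by 0.57 on the log2 scale (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0439 and 0.0350). Both calls were lost without sptl-3 replicate 1 (−0.41 and −0.44) and without wild-type replicate 1 (−0.42 and −0.33). That of sptl-1 was lost also without wild-type replicate 2 (−0.65) and sptl-3 replicate 2 (−0.69). Both were lost as well with RLE factors (−0.49 and −0.52), library totals (−0.14 and −0.16) and DESeq2 (−0.49 and −0.52), and that of sptl-2 with thinned libraries (−0.43). The sptl-2 gene in the sptl-1 mutant (−0.39), the sptl-3 gene in the sptl-1 mutant (0.02), the sptl-1 gene in the sptl-2 mutant (−0.41) and the sptl-3 gene in the sptl-2 mutant (0.27) did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.234, 0.951, 0.152 and 0.201). The last passed with library totals (0.54). The values are counts over whole genes, which can include exons outside a deletion.

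**Figure D2:**
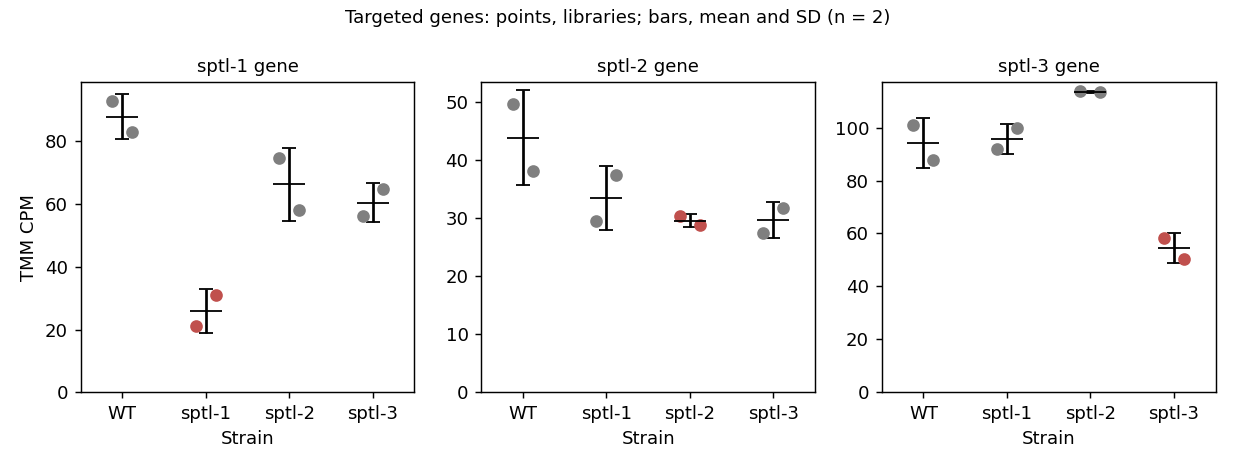
TMM-scaled CPM of the sptl-1, sptl-2 and sptl-3 genes in each worm library, with points for the 2 libraries of each strain and bars for their mean and SD. The sptl-1 gene fell from a mean of 87.9 in wild type to 26.0 in its own mutant, sptl-2 from 43.8 to 29.6 (also 29.6 in the sptl-3 mutant) and sptl-3 from 94.3 to 54.4.

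The largest changes of named genes in the sptl-1 mutant were falls. The serpentine receptor gene srw-85 (WBGene00005832) fell from 103.8 ± 9.22 to 2.79 ± 0.217 CPM (SD, n = 2), a log2 change of −5.22 (SE 0.19). The CUB-domain gene dod-24 (WBGene00007875) fell from 324 ± 3.78 to 27.3 ± 1.44 CPM (SD, n = 2; −3.57, SE 0.15), and the C-type lectin gene clec-2 had a log2 change of −3.90 and the insulin-like gene ins-39 one of −3.497. The lipocalin-related genes lpr-4, lpr-3 and lpr-6 stood at −3.37, −3.33 and −3.10, and the cytochrome P450 gene cyp-37B1 at −3.20. The gene lfor-1 rose by 2.16 (SE 0.57, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0360), a call lost without any 1 of the 4 libraries (1.87 to 2.51), with DESeq2 (2.16) and with thinned libraries (2.50). The next rise was that of the carnitine palmitoyltransferase gene cpt-4 (WBGene00019644), from 18.8 ± 2.16 to 66.0 ± 2.02 CPM (SD, n = 2; 1.81, SE 0.17), followed by chca-1 (1.68), cyp-33C8 (1.52), the zinc finger gene egl-46 (1.49), gei-15 (1.46) and cfh-1 (1.45). The adjusted p of the other genes lay between 3.1e-09 for srw-85 and 0.00140 for chca-1 (edgeR quasi-likelihood, Benjamini-Hochberg). Of 18910 genes tested, 538 rose and 648 fell, 161 and 358 of them by at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). The total of 1186 calls became 2934 in a fit on the compared groups alone (1515 higher and 1419 lower) and 750 in thinned libraries, a setting added after the data were seen. It was 275 without wild-type replicate 1, 368 without wild-type replicate 2, 509 without sptl-1 replicate 1 and 387 without sptl-1 replicate 2. With library totals alone the median of all genes was −0.07 and the calls were 374 higher and 750 lower, and without a filter they were 900 and 825.

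Called genes of the sphingolipid list were mostly lower in the sptl-1 mutant: of 30 tested, 1 rose and 7 fell (11 changed when adjusted over the list alone), with a median log2 change of −0.24. The list holds the 3 sptl genes, and the targeted sptl-1 gene is 1 of the 7. Without the sptl genes, an alternative added after the data were seen, 1 rose and 6 fell of 27, with a median of −0.23 (camera adjusted p = 5.4e-05; adjusted p = 0.221 with an estimated correlation). For the full sphingolipid list, camera gave adjusted p = 2.7e-06, and adjusted p = 0.219 with an estimated correlation (4.0e-07 to 0.219 over its alternatives). The falls included the acid ceramidase gene asah-1 (WBGene00010769), which went from 253 ± 2.82 to 55.9 ± 1.96 CPM (SD, n = 2; −2.18, SE 0.22), and the acid sphingomyelinase gene asm-2 (−1.68). Intestine markers fell, with 18 of 32 lower and 0 higher (22 adjusted over the list alone), a median of −0.93 (camera adjusted p = 2.5e-32; adjusted p = 0.219 with an estimated correlation; 1.8e-36 to 0.219 over its alternatives), and the aspartic protease gene asp-14 down from 2208 ± 102 to 364 ± 15.9 CPM (SD, n = 2). Of 324 innate immunity genes 11 rose and 55 fell (92 adjusted over the list alone), with a median of −0.35. Its members included clec-50 at −3.04. For the immunity list, camera gave adjusted p = 8.8e-10, and adjusted p = 0.219 with an estimated correlation (8.5e-10 to 0.219 over its alternatives). Of 79 genes of lipid desaturation, oxidation and lipases, 3 rose and 16 fell (29 adjusted over the list alone), with a median of −0.15. Examples were the lipase gene lipl-1 at −2.84 and the desaturase gene fat-7 at −2.16. For the lipid oxidation and lipase list, camera gave adjusted p = 0.00785, fry adjusted p = 0.0884, and adjusted p = 0.428 with an estimated correlation (0.00468 to 0.428 over its alternatives). Among 208 xenobiotic metabolism genes 8 rose and 20 fell (44 adjusted over the list alone), with a median of −0.13. Among them was the transporter gene pgp-6 at −1.59. For the xenobiotic list, camera gave adjusted p = 0.0117, fry adjusted p = 0.0856, and 0.112 by camera without wild-type replicate 2, and adjusted p = 0.410 with an estimated correlation (0.00163 to 0.410 over its alternatives). Of 35 DAF-16 associated stress genes 0 rose and 2 fell (2 adjusted over the list alone), sod-3 and sod-5, with a median of −0.11. For the DAF-16 list, camera gave adjusted p = 0.0413, 0.150 without sptl-1 replicate 1 and 0.233 without wild-type replicate 1, and adjusted p = 0.267 with an estimated correlation (0.0268 to 0.267 over its alternatives). The calls of sod-3 and sod-5 (−0.79 and −0.64) were lost without any 1 of the 4 libraries, with values from −0.95 to −0.62 and from −0.73 to −0.55, and with thinned libraries (−0.64 and −0.63).

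Called genes of the collagen and molt lists were lower more often than higher in the sptl-1 mutant, and those of the muscle and neuropeptide lists higher more often than lower. The collagen, molt and neuropeptide lists did not pass fry. Stage is not given in the sources used here, so it was not separated from genotype for these lists in any mutant. Of 173 cuticle collagen genes 10 rose and 20 fell (39 adjusted over the list alone), with a median of −0.14. Members included col-17 at −3.09, dpy-3 at −2.96 and sqt-2 at −2.80. For the collagen list, camera gave adjusted p = 0.00442, fry adjusted p = 0.199, and 0.0573 by camera without sptl-1 replicate 2, and adjusted p = 0.499 with an estimated correlation (2.6e-04 to 0.499 over its alternatives). Of 42 molt and heterochronic genes 1 rose and 9 fell (12 adjusted over the list alone), with a median of −0.11. Examples were noah-2 at −2.65 and mlt-11 at −2.07. For the molt list, camera gave adjusted p = 0.00110, fry adjusted p = 0.0670, and adjusted p = 0.321 with an estimated correlation (4.0e-04 to 0.321 over its alternatives). Of 18 body wall muscle markers 3 rose and 0 fell (8 adjusted over the list alone), with the myosin gene myo-3 up from 519 ± 42.9 to 1050 ± 6.98 CPM (SD, n = 2) and a median of 0.33. For the muscle list, camera gave adjusted p = 7.4e-06, and adjusted p = 0.267 with an estimated correlation (7.6e-06 to 0.267 over its alternatives). Of 103 neuropeptide and insulin genes 18 rose and 2 fell (29 adjusted over the list alone), with a median of 0.26. For the neuropeptide list, camera gave adjusted p = 6.7e-06, fry adjusted p = 0.172, and adjusted p = 0.447 with an estimated correlation (1.3e-07 to 0.447 over its alternatives). Of 67 genes of cilia and intraflagellar transport 2 rose, ccep-290 (0.73) and nphp-1 (0.77), and 0 fell (1 adjusted over the list alone), with a median of 0.22. For the cilia list, camera gave adjusted p = 0.00304, and adjusted p = 0.267 with an estimated correlation (9.2e-04 to 0.267 over its alternatives). Both transition zone genes lost their call without any 1 of the 4 libraries, with values from 0.67 to 0.80 and from 0.70 to 0.86. That of nphp-1 was also lost with library totals (0.71), DESeq2 (0.78) and thinned libraries (0.95).

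The remaining lists did not pass the camera test in the sptl-1 mutant. Branched-chain and very long chain fatty acid synthesis had 1 of 15 genes higher and 0 lower (1 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.260). Heat shock and unfolded protein response genes went both ways, with 7 of 63 higher and 4 lower (14 adjusted over the list alone), among them ckb-2 at 1.44 and abu-8 at −2.02 (not called at −1.90 in thinned libraries), and their median of 0.05 turned negative with library totals (camera adjusted p = 0.118). Ribosomal protein genes had 1 of 81 higher and 0 lower (1 adjusted over the list alone), with a median of 0.06 that also turned negative with library totals (camera adjusted p = 0.224, 0.0399 without sptl-1 replicate 1; 0.0399 to 0.875 over its alternatives). Major sperm proteins had 0 of 37 higher and 0 lower (0 adjusted over the list alone), with a median of −0.01 (camera adjusted p = 0.855). Oocyte and early embryo markers had 2 of 39 higher and 2 lower (5 adjusted over the list alone), with a median of −0.22 (camera adjusted p = 0.281). Vitellogenins had 0 of 6 higher and 0 lower (0 adjusted over the list alone), with a median of −0.19 (camera adjusted p = 0.574). No member of the sperm or vitellogenin lists had an unadjusted edgeR p below 0.05 (0 genes), and DESeq2 called 0. Germline markers had 1 of 35 higher and 0 lower (0 adjusted over the list alone), with a median of −0.22 (camera adjusted p = 0.0827, 0.00730 without sptl-1 replicate 1; 0.00730 to 0.492 over its alternatives). Pan-neuronal markers had 1 of 12 higher and 0 lower (1 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.133).

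The largest changes of named genes in the sptl-2 mutant were rises. The serpentine receptor gene sri-31 (WBGene00005543) went from 1.11 ± 0.471 to 33.3 ± 4.11 CPM (SD, n = 2), a log2 change of 4.90 (SE 0.38). The synaptonemal complex gene syp-1 (WBGene00006375) went from 2.30 ± 1.35 to 49.2 ± 0.904 CPM (SD, n = 2), a change of 4.43 (SE 0.29). The genes bath-2 (4.42), ilys-2, an invertebrate-type lysozyme (3.82), enu-3.2 (3.23), lotr-1 (3.23), zhp-2 (3.19) and fbxa-136 (3.16) followed. The largest falls were those of ins-39 (−3.11), nspg-7.2 (−3.09), clec-2 (−2.50), asp-14 (−2.22), cyp-37B1 (−2.21), clec-3 (−2.12), the glutathione S-transferase gene gst-34 (−2.12) and fat-7 (−2.09). The adjusted p of these genes lay between 3.0e-07 for lotr-1 and 0.000989 for ins-39 (edgeR quasi-likelihood, Benjamini-Hochberg). Of the genes tested 1480 rose and 1756 fell, 1074 and 456 of them by at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). The total of 3236 calls was 790 without wild-type replicate 1, 1258 without wild-type replicate 2 and 1650 without sptl-2 replicate 2. With library totals alone the median of all genes was 0.24 and the calls were 2706 higher and 690 lower. The balance also turned with RLE factors (1538 and 1462) and with the compared groups alone (1894 and 1370).

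Ribosomal protein genes fell together in the sptl-2 mutant, 67 of 81 with 1 higher (79 adjusted over the list alone), with a median of −0.82. Among them were rps-12 at −1.32 and rpl-22 at −1.23. For the ribosomal list, camera gave adjusted p = 8.9e-30, and adjusted p = 0.321 with an estimated correlation (7.6e-51 to 0.321 over its alternatives). Their summed level was 158669 ± 1826 CPM in wild type, 161837 ± 7148 in sptl-1, 94850 ± 18939 in sptl-2 and 72449 ± 10377 in sptl-3 (SD, n = 2). The exception, rpl-42 (1.60), lost its call without any 1 of the 4 libraries, with values from 1.55 to 1.72. Of 103 neuropeptide and insulin genes 0 rose and 44 fell (54 adjusted over the list alone), with a median of −0.59. Its members included nlp-20 at −1.55. For the neuropeptide list, camera gave adjusted p = 1.0e-14, and adjusted p = 0.295 with an estimated correlation (2.3e-17 to 0.295 over its alternatives). Of 32 intestine markers 1 rose and 16 fell (20 adjusted over the list alone), with asp-14 down to 475 ± 26.0 CPM (SD, n = 2) and a median of −0.43. For the intestine list, camera gave adjusted p = 2.6e-10, and adjusted p = 0.267 with an estimated correlation (1.1e-12 to 0.267 over its alternatives). Genes of lipid desaturation, oxidation and lipases had 6 of 79 higher and 18 lower (28 adjusted over the list alone), with a median of −0.28. Examples were lipl-1 at −1.80 and acdh-1 at −1.77. For the lipid oxidation and lipase list, camera gave adjusted p = 0.000394, and adjusted p = 0.362 with an estimated correlation (1.6e-05 to 0.362 over its alternatives). DAF-16 associated stress genes had 0 of 35 higher and 8 lower (8 adjusted over the list alone), with sod-5 at −1.16 and a median of −0.22 that turned positive with library totals. For the DAF-16 list, camera gave adjusted p = 0.0192, 0.0529 with library totals and 0.0757 without wild-type replicate 1, and adjusted p = 0.267 with an estimated correlation (0.00826 to 0.267 over its alternatives).

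Called genes of the molt, collagen and vitellogenin lists were mostly higher in the sptl-2 mutant, where stage was not separated from genotype. Of 42 molt and heterochronic genes 21 rose and 0 fell (27 adjusted over the list alone), with a median of 0.79. Among them were the period-like gene lin-42 at 2.22, mlt-8 at 2.11 and noah-2 at 2.098. For the molt list, camera gave adjusted p = 7.4e-15, and adjusted p = 0.221 with an estimated correlation (6.1e-20 to 0.221 over its alternatives). Of 173 cuticle collagen genes 49 rose and 4 fell (63 adjusted over the list alone), with col-93 up to 63.8 ± 12.5 CPM (SD, n = 2), col-159 at 2.92, col-13 at 2.54 and a median of 0.50. For the collagen list, camera gave adjusted p = 1.5e-10, and adjusted p = 0.295 with an estimated correlation (6.1e-17 to 0.295 over its alternatives). Of 6 vitellogenin genes, which encode yolk proteins made in the adult intestine, 4 rose and 0 fell (6 adjusted over the list alone), with a median of 1.35. Members included vit-5 at 1.83 and vit-2 at 1.39, from 14.1 and 13.1 CPM. For the vitellogenin list, camera gave adjusted p = 1.4e-06, and adjusted p = 0.267 with an estimated correlation (7.2e-09 to 0.267 over its alternatives). Germline markers had 6 of 35 higher and 1 lower (8 adjusted over the list alone), with a median of 0.21. An example was the helicase gene glh-1 at 1.504. For the germline list, camera gave adjusted p = 0.00464, and adjusted p = 0.378 with an estimated correlation (5.5e-04 to 0.378 over its alternatives).

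The other lists did not pass the camera test in the sptl-2 mutant, and several medians turned with the scaling. Sphingolipid genes had 3 of 30 higher, with ttm-5 at 1.35, and 5 lower, with asm-2 at −1.23, asah-2 at −1.20 and the targeted sptl-2 gene (11 adjusted over the list alone), and their median of −0.04 turned positive with library totals (camera adjusted p = 0.347). Branched-chain and very long chain fatty acid synthesis had 2 of 15 higher and 2 lower (4 adjusted over the list alone), with a median of −0.08 that turned positive with library totals and a mean of 0.13 (camera adjusted p = 0.634). Cilia genes had 4 of 67 higher and 3 lower (1 adjusted over the list alone), with a median of −0.05 that turned positive with library totals (camera adjusted p = 0.897). Innate immunity genes had 34 of 324 higher and 45 lower (88 adjusted over the list alone), with irg-2 at 2.67 and a median of 0.02, while the camera test pointed down (camera adjusted p = 0.894). Xenobiotic metabolism had 26 of 208 higher and 22 lower (53 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.324). Heat shock and unfolded protein response had 6 of 63 higher, with abu-14 at 2.37, and 8 lower (15 adjusted over the list alone), with a median of 0.03 (camera adjusted p = 0.360). The sperm list had 5 of 37 higher, with ssp-16 at 2.30, and 0 lower (5 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.0805). Oocyte and early embryo markers had 7 of 39 higher, with cbd-1 at 1.25, and 2 lower (10 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.0645, 0.0132 without sptl-2 replicate 2; 0.0132 to 0.492 over its alternatives). Body wall muscle markers had 2 of 18 higher and 3 lower, the myosin light chain genes mlc-2 (−0.79), mlc-3 (−0.77) and mlc-1 (−0.55) (5 adjusted over the list alone), with a median of −0.14 that turned positive with library totals (camera adjusted p = 0.333). The call of mlc-1 was lost without wild-type replicate 1 (−0.52), wild-type replicate 2 (−0.53) or sptl-2 replicate 2 (−0.42), and with library totals (−0.28). Pan-neuronal markers had 0 of 12 higher and 0 lower (0 adjusted over the list alone), with a median of −0.24 that turned positive with library totals (camera adjusted p = 0.187, fry adjusted p = 0.0329; 0.0329 to 0.754 over its alternatives). At an unadjusted edgeR p below 0.05 the latter list had 5 genes, and DESeq2 called 0.

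The sptl-3 mutant differed most from wild type in number of genes, and its largest rises of named genes were all of histone genes. The transcripts of his-16, his-1, his-18, his-17, his-64, his-2, his-5 and his-46 (WBGene00001930) rose by between 6.31 (his-16) and 4.70 (his-46) on the log2 scale. The level of his-2 (WBGene00001876) went from 4.97 ± 1.67 to 142 ± 37.4 CPM (SD, n = 2; 4.84, SE 0.26). Many histone genes have near-identical copies between which reads can be divided, so the values of single members are uncertain. The largest falls were those of clec-2 (−4.28), srw-85 (−4.09), the saposin-like gene spp-12 (−4.01), dod-24 (−3.72), hpo-26 (−3.64), the metallothionein gene mtl-2 (−3.63), scl-5 (−3.62) and ins-39 (−3.61). The level of spp-12 (WBGene00004997) went from 396 ± 0.188 to 24.6 ± 5.34 CPM (SD, n = 2; SE of the log2 change 0.28). The adjusted p of these genes lay between 3.6e-08 for dod-24 and 0.000502 for ins-39 (edgeR quasi-likelihood, Benjamini-Hochberg). Of the genes tested 2237 rose and 3585 fell, 1444 and 1845 of them by at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). The total of 5822 calls was 3199 without wild-type replicate 1, 3572 without wild-type replicate 2 and 3288 without sptl-3 replicate 1. With library totals alone the median of all genes was 0.38 and the calls turned to 5124 higher and 1819 lower.

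Ribosomal protein genes fell almost without exception in the sptl-3 mutant, 79 of 81 with 1 higher (81 adjusted over the list alone), with a median of −1.33. Among them were rpl-41.2 at −2.30 and rpl-22 at −2.03. For the ribosomal list, camera gave adjusted p = 3.3e-42, and adjusted p = 0.271 with an estimated correlation (5.3e-57 to 0.271 over its alternatives). Intestine markers had 0 of 32 higher and 23 lower (24 adjusted over the list alone), with asp-14 down to 283 ± 10.2 CPM (SD, n = 2), asp-12 at −2.32 and a median of −1.27. For the intestine list, camera gave adjusted p = 6.1e-25, and adjusted p = 0.221 with an estimated correlation (7.5e-25 to 0.221 over its alternatives). Neuropeptide and insulin genes had 4 of 103 higher and 65 lower (76 adjusted over the list alone), with a median of −1.15. Members included flp-33 at −3.16 and ins-28 at −3.15. For the neuropeptide list, camera gave adjusted p = 4.0e-20, and adjusted p = 0.267 with an estimated correlation (9.0e-24 to 0.267 over its alternatives). Body wall muscle markers had 0 of 18 higher and 12 lower (12 adjusted over the list alone), with a median of −0.71. Examples were the troponin genes tni-4 at −2.27 and tnt-4 at −1.81. For the muscle list, camera gave adjusted p = 5.4e-08, and adjusted p = 0.267 with an estimated correlation (8.8e-09 to 0.267 over its alternatives). Genes of lipid desaturation, oxidation and lipases had 8 of 79 higher and 38 lower (51 adjusted over the list alone), with a median of −0.54. Among them were lipl-1 at −2.64, acs-3 at −2.04 and acs-10 at 1.95. For the lipid oxidation and lipase list, camera gave adjusted p = 0.000104, and adjusted p = 0.321 with an estimated correlation (4.7e-06 to 0.321 over its alternatives). Innate immunity genes had 27 of 324 higher and 95 lower (127 adjusted over the list alone), with a median of −0.24 that became 0.16 with library totals. For the immunity list, camera gave adjusted p = 0.00416, and adjusted p = 0.267 with an estimated correlation (4.5e-05 to 0.267 over its alternatives).

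Called genes of the sphingolipid list were mostly lower in the sptl-3 mutant, 11 of 30 with 1 higher (14 adjusted over the list alone), and the median of −0.35 became 0.05 with library totals. The 11 include the targeted sptl-3 gene and the calls of sptl-1 and sptl-2, which several alternatives ended. Without the sptl genes 1 of 27 rose and 8 fell, with a median of −0.23 (camera adjusted p = 0.0329; adjusted p = 0.271 with an estimated correlation). For the full sphingolipid list, camera gave adjusted p = 0.0123, 0.0772 with library totals, and adjusted p = 0.267 with an estimated correlation (0.00494 to 0.267 over its alternatives). The ceramidase gene asah-1 went to 39.8 ± 13.2 CPM (SD, n = 2; −2.67, SE 0.24) and asah-2 from 64.7 ± 1.18 to 11.1 ± 3.56 CPM (SD, n = 2; −2.54, SE 0.21), while ttm-5, a homolog of dihydroceramide desaturases, rose by 1.87. Molt and heterochronic genes had 18 of 42 higher and 3 lower (24 adjusted over the list alone), with a median of 0.47. Members included the patched-related genes ptr-9 at 1.53, ptr-1 at 1.40 and ptr-4 at 1.27. For the molt list, camera gave adjusted p = 0.000306, and adjusted p = 0.295 with an estimated correlation (3.9e-08 to 0.295 over its alternatives). The sperm list of major sperm proteins and other sperm genes had 8 of 37 higher and 0 lower. Adjusted over the list alone, 5 changed, and the median was 0.32. Examples were ssp-16 at 3.70 and spe-29 at 2.21, neither of them of the msp class of major sperm protein genes. For the sperm list, camera gave adjusted p = 0.0108, 0.0747 with library totals, and adjusted p = 0.377 with an estimated correlation (0.00572 to 0.377 over its alternatives).

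Other lists did not pass the camera test in the sptl-3 mutant. Cilia and intraflagellar transport had 11 of 67 genes higher and 4 lower, among them ift-43 (−1.22) and tbb-4 (−1.17) (15 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.0645, 0.0348 with library totals; 0.0348 to 0.371 over its alternatives). Branched-chain and very long chain fatty acid synthesis had 2 of 15 higher and 2 lower, hpo-8 (−1.55) and let-767 (−0.76) (4 adjusted over the list alone), with a median of −0.10 that turned positive with library totals (camera adjusted p = 0.751). Xenobiotic metabolism had 16 of 208 higher, with cyp-35B2 at 2.86, and 58 lower, with gst-28 at −2.46 (81 adjusted over the list alone), and a median of −0.19 that turned positive with library totals (camera adjusted p = 0.0778, 0.00798 without sptl-3 replicate 2 and 0.0118 without wild-type replicate 1; fry adjusted p = 0.0317; 0.00798 to 0.492 over its alternatives). Cuticle collagens had 10 of 173 higher, with col-93 at 1.85, and 18 lower (23 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.486, 0.0446 without sptl-3 replicate 1; 0.0446 to 0.937 over its alternatives). Heat shock and unfolded protein response had 7 of 63 higher, with abu-14 at 2.93, and 16 lower, with hsp-12.2 at −3.03 (23 adjusted over the list alone), and a median of −0.17 that turned positive with library totals (camera adjusted p = 0.706, fry adjusted p = 0.0359; 0.0359 to 0.898 over its alternatives). DAF-16 associated stress genes had 6 of 35 higher and 12 lower, with dct-18 at −1.72 (18 adjusted over the list alone), and a median of −0.09 that turned positive with library totals (camera adjusted p = 0.188, fry adjusted p = 0.0136; 0.0136 to 0.381 over its alternatives).

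In the sptl-3 mutant oocyte and early embryo genes had 4 of 39 higher, with perm-1 at 1.64, and 5 lower, with cpg-9 at −2.28 (9 adjusted over the list alone). Their mean was 0.01, and their median of −0.04 turned positive with library totals and with RLE factors (camera adjusted p = 0.706). The germline list had 3 of 35 higher and 3 lower, him-5 (−1.83), glh-1 (−1.21) and him-4 (−0.75) (5 adjusted over the list alone). Its median of −0.19 turned positive with library totals (camera adjusted p = 0.880), and its members' tissue was not tested. Vitellogenins had 3 of 6 higher, with vit-5 at 2.02, and 0 lower (3 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.0827). Pan-neuronal markers had 2 of 12 higher, with the kinesin gene unc-104 at 0.66, and 4 lower, with sng-1 at −0.996 (8 adjusted over the list alone), and a median of −0.05 that turned positive with library totals (camera adjusted p = 0.943).

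**Figure D3:**
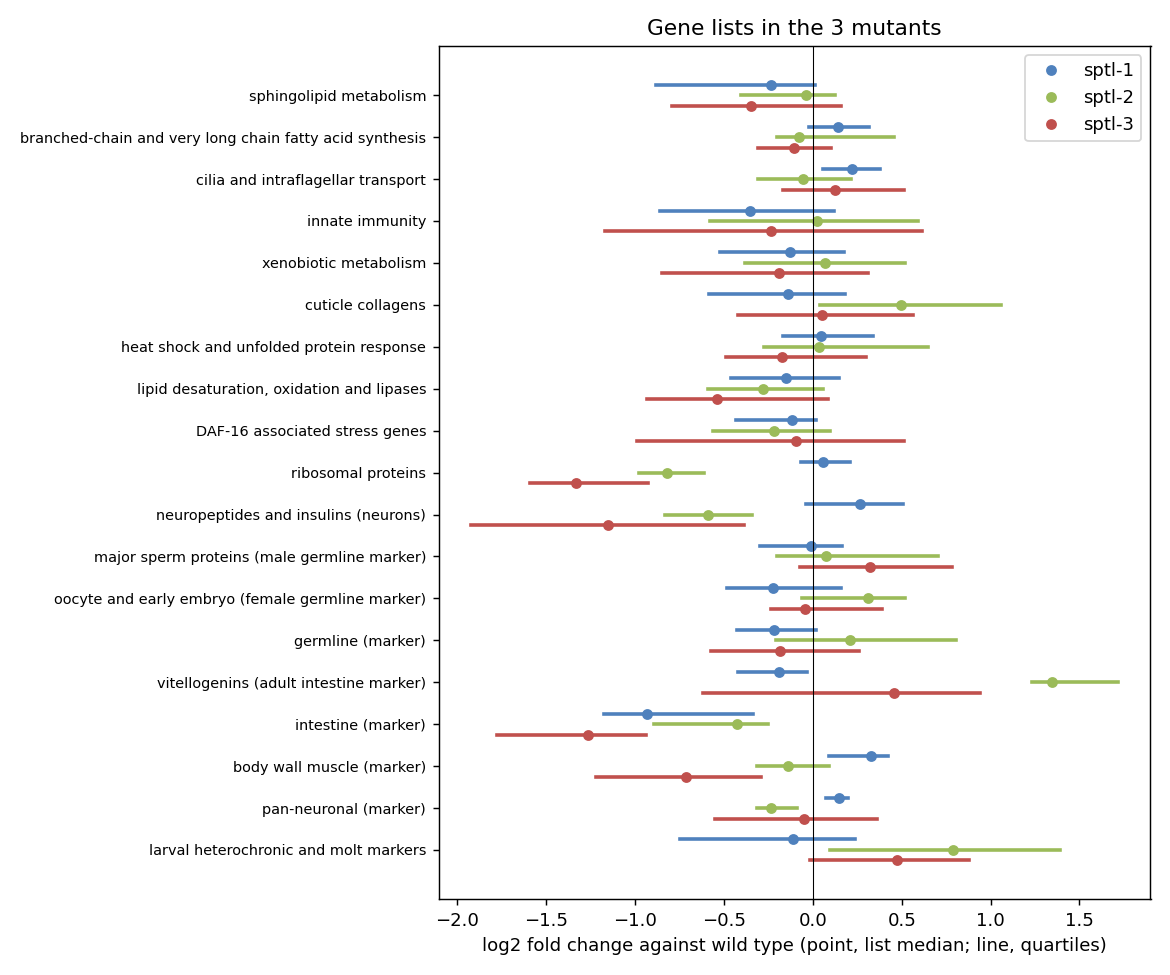
Median log2 fold change of the tested members of 19 gene lists in each sptl mutant against wild type, with lines from the lower to the upper quartile of the members. Ribosomal protein genes stand at 0.06, −0.82 and −1.33 in sptl-1, sptl-2 and sptl-3 (the value of sptl-1 turned negative with library totals), intestine markers at −0.93, −0.43 and −1.27, and molt genes at −0.11, 0.79 and 0.47.

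**Figure D4:**
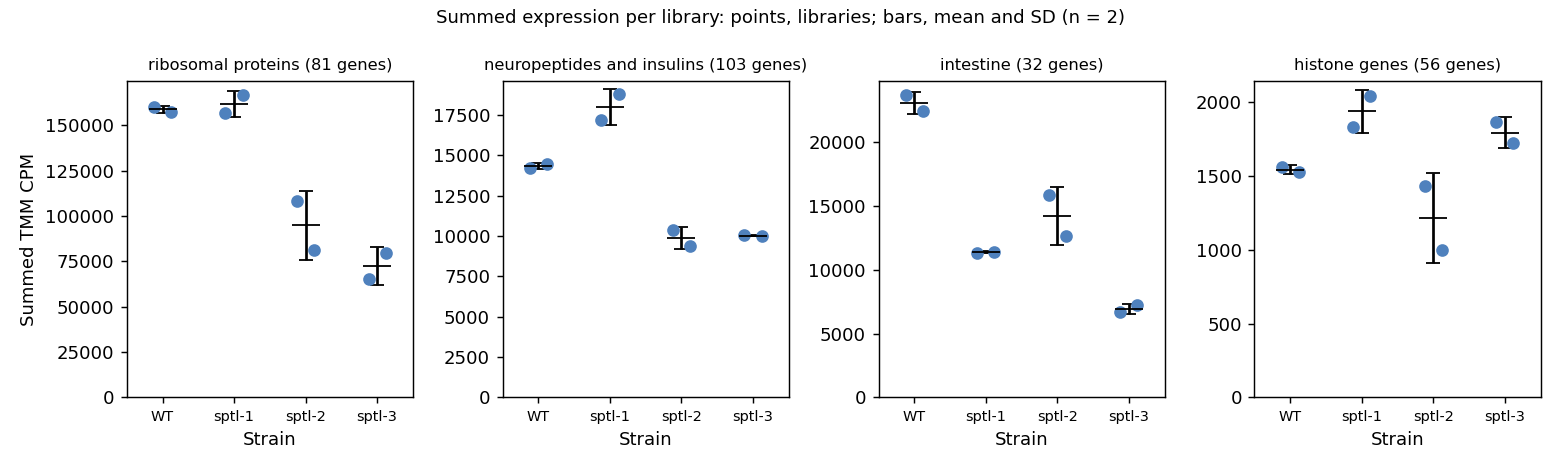
Summed TMM-scaled CPM of 4 gene groups in each worm library, with points for the 2 libraries of each strain and bars for their mean and SD. Ribosomal protein genes held 158669 in wild type and 72449 in sptl-3, intestine markers 23031 and 6939, neuropeptide and insulin genes 14345 and 10037, and histone genes 1544 and 1795.

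The 3 mutants shared part of their changes. The sptl-2 and sptl-3 mutants had 721 genes higher and 1393 lower in common, where independent lists would share 175 and 333. The sptl-1 mutant shared 100 higher and 258 lower genes with sptl-2 (42.1 and 60.2 for independent lists) and 145 higher and 390 lower genes with sptl-3 (63.6 and 122.8). Opposite calls were made for 114 genes lower in sptl-1 and higher in sptl-2 and for 45 the other way, where independent lists would share 50.7 and 49.96. Higher in sptl-1 and lower in sptl-3 were 121 genes, and 35 were the other way (102 and 76.7 for independent lists). Higher in sptl-2 and lower in sptl-3 were 48, and 14 were the other way (281 and 208). In all 3 mutants 61 genes were called higher and 226 lower, and ins-39, clec-2, lipl-1 and asp-14 were among the latter. All 3 comparisons use the same 2 wild-type libraries, which could not be split into sets of 2. In 30 simulations of unchanged strains against these controls the correlation of log2 changes was 0.52, 0.44 and 0.41 for sptl-1 with sptl-2, sptl-1 with sptl-3 and sptl-2 with sptl-3. The observed Pearson correlations across genes were 0.26, 0.26 and 0.64. The covariances were 0.107, 0.142 and 0.458, against 0.0679, 0.0676 and 0.0678 simulated. Only the correlation of sptl-2 with sptl-3 thus lay above its simulated value, while the covariances lay above in all 3 pairs. Part of the overlaps may come from the shared controls, and strain was not separated from depth, lowest in sptl-2 and sptl-3.

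Tested directly against each other, the mutants differed on many genes. Between sptl-1 and sptl-2, 2450 genes were higher in sptl-1 and 1937 lower. Between sptl-1 and sptl-3 the numbers were 3721 and 2406, and between sptl-2 and sptl-3, 1713 higher in sptl-2 and 707 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). Neuropeptide and insulin genes were higher in sptl-1 than in sptl-2 (median 0.80) and than in sptl-3 (median 1.32; camera adjusted p = 5.8e-24 and 1.4e-31; adjusted p = 0.267 for both with an estimated correlation). Of 42 molt genes 23 were called lower and 1 higher in sptl-1 than sptl-2 (median −0.77), and 20 and 4 than sptl-3 (median −0.51). Camera gave adjusted p = 8.7e-19 and 3.8e-08 (0.219 and 0.267 with an estimated correlation). With library totals alone the medians of all genes moved to −0.32, −0.48 and −0.12. The calls became 787 higher and 3813 lower, 1716 and 6219, and 1254 and 1151. In fits on the compared groups alone they were 1446 and 1708 between sptl-1 and sptl-2, and 1431 in total between sptl-2 and sptl-3. Thinned libraries gave 2808 calls between sptl-1 and sptl-2. The totals of calls fell to 1595 without sptl-1 replicate 2 and 2439 without sptl-2 replicate 2 between sptl-1 and sptl-2. They fell to 3488 without sptl-1 replicate 2 and 3554 without sptl-3 replicate 1 between sptl-1 and sptl-3, and to 950 without sptl-2 replicate 1 and 697 without sptl-3 replicate 1 between sptl-2 and sptl-3.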

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

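The molting and composition tests below were chosen after the result each measures was seen, thinning and totals without the 2 most abundant genes were added to the alternatives after the data were seen, and so was the choice of mutant differences listed here. For the differences between mutants 3 criteria were tried in turn: an adjusted p below 0.05 with both the preset and an estimated correlation left 0 of 57 list tests, an adjusted p below 1e-10 with the preset correlation left 8, and the criterion used, opposite calls against wild type together with a called difference, left 6 lists and 35 of 438 gene tests. Without the condition on opposite calls 35 list tests and 283 gene tests passed. None of the 6 list calls held with an estimated correlation (0 of 57 tests).

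Transcripts and footprints differed between 30 and 90 min after deflagellation, for 804 genes in the RNA-seq (525 without 90 min replicate 1) and 3399 in the Ribo-seq. The mutants differed from each other on 4387 genes between sptl-1 and sptl-2 (1595 without sptl-1 replicate 2 and 2439 without sptl-2 replicate 2), on 6127 between sptl-1 and sptl-3 (3488 without sptl-1 replicate 2 and 3554 without sptl-3 replicate 1), and on 2420 between sptl-2 and sptl-3 (950 without sptl-2 replicate 1 and 697 without sptl-3 replicate 1). Cuticle collagens had opposite calls in sptl-1 and sptl-2, with a median difference of −0.49 (camera adjusted p = 1.1e-13; 0.267 with an estimated correlation), though the sptl-1 call was lost without sptl-1 replicate 2 (camera adjusted p = 0.0573; 2.6e-04 to 0.499 over its alternatives). Neuropeptide and insulin genes differed by a median of 0.80 between sptl-1 and sptl-2 and of 1.32 between sptl-1 and sptl-3, and the molt list by −0.77 and −0.51. Body wall muscle markers differed by 1.05 between sptl-1 and sptl-3 (camera adjusted p = 4.7e-16; 0.221 with an estimated correlation).

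Single genes are given here because they had opposite calls against wild type together with a called difference. Between sptl-1 and sptl-2 the log2 differences were −5.40 for col-17, −5.24 for lpr-3, −4.92 for lpr-4, −4.90 for sqt-2, −4.80 for lpr-6, −4.74 for noah-2, −4.48 for dpy-3, −4.07 for mlt-11, −4.07 for mlt-8, −3.57 for lin-42, −3.53 for ptr-4, −3.08 for abu-12, −2.69 for abu-13 and −1.91 for cbd-1, and 1.90 for rpl-11.1 and 2.20 for cpg-9. Between sptl-1 and sptl-3 they were −4.25 for lpr-4, −4.20 for lpr-6, −3.87 for col-17, −3.59 for noah-2, −3.002 for mlt-8, −2.96 for ptr-4, −2.55 for abu-12, −2.26 for pgp-6, −2.18 for lin-42, −1.87 for abu-13 and −1.24 for sod-5, and 1.53 for mup-2, 1.75 for cpg-8, 2.22 for nlp-33, 2.33 for rpl-11.1 and 3.30 for cpg-9. Between sptl-2 and sptl-3 they were −1.60 for pgp-6, −1.76 for sod-5 and 2.72 for glh-1. Against wild type, the sptl-1 calls of sod-5 (−0.73 to −0.55) and mlt-8 (−2.22 to −1.66) were lost without any 1 of the 4 libraries. Those of abu-12 (−1.40 to −1.12), rpl-11.1 (0.81 to 0.91), nlp-33 (1.12 to 1.42), cpg-9 (0.94 to 1.04), cpg-8 (0.65 to 0.71) and mup-2 (0.67 to 0.75) were lost without sptl-1 replicate 2, wild-type replicate 1 or wild-type replicate 2.

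In sptl-3, with the shallowest libraries, ribosomal protein genes were lower and 43 of 56 histone genes higher, while the 5 most abundant fell. Thinned to the smallest total, the 8 worm libraries gave medians of 3.23 (44 histone genes) and −1.23 (ribosomal proteins). Fewer counts alone were not the cause. The DNA replication genes had a median of −0.048 over 19 genes, which argues against more cells in S phase. A library preparation that kept more RNA without a poly(A) tail cannot be told apart from an effect of the strain, because only 2 spliced leader genes could be tested, sls-2.5 (−0.71) and sls-2.16 (−0.89), with a median of −0.80. Effects of losing sptl-3 on the level or tails of histone transcripts, or of low library yield, stay open and were not tested.

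Intestine markers were lower in all 3 mutants. Vitellogenins had medians of −0.19, 1.35 and 0.46 in sptl-1, sptl-2 and sptl-3 and were called higher in sptl-2 (camera adjusted p = 1.4e-06, 0.267 with an estimated correlation). In wild type vit-5 stood at 14.1 and asp-14 at 2208 CPM, which limits comparing the lists. Leaving out either wild-type library kept each intestine median at or below −0.36, so the pattern did not rest on 1 of these libraries. A place of all 3 mutants on the same side of wild type in the molting cycle cannot be told apart from other causes. The molt list was called higher in 2 mutants and lower in sptl-1 with a preset correlation. The sptl-1 call was lost with fry (adjusted p = 0.0670). In this list sptl-1 differed from sptl-2 and sptl-3 (fry adjusted p = 0.0115 and 0.0136), which does not place it below wild type. With an estimated correlation 0 calls held (camera adjusted p = 0.321, 0.221 and 0.295). No list passed that test, so this decides nothing. A shift of both wild-type libraries alone cannot be told apart from an effect shared by the mutants: 3 of 3 tests between mutants passed with a preset correlation and 0 with an estimated one, and no other wild-type library was analysed here. A difference in stage, unknown here, and an effect of lost serine palmitoyltransferase on the intestine stay open and were not tested.

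Translational efficiency was called higher more often than lower after deflagellation. At 30 min the share of higher calls was at least 0.809 without each non-treated library, which argues against 1 library as the whole cause. It was 0.891 above the median RNA-seq mean count of 10.9. Most calls lay there (139 higher and 17 lower, below it 4 and 9), so few counts stay open. The 2 most abundant RNA-seq genes cannot be told apart from other causes: the share was 0.840 with both taken out of the table (142 and 27), but only 1 of them was tested for efficiency, and the removal moved the scaling at 30 min by a log2 of only 0.0377, so it decides nothing. An effect of the composition factors cannot be told apart from one of the cells: with library totals that left out these 2 genes as the only scaling the share was 0.556 at 30 min (129 higher and 103 lower, against 143 and 26), and the balance turned at 60 min (121 and 310) and 90 min (129 and 511), but through more lower calls, under a scaling that shifts all genes alike. Which scaling is closer to the cells was not tested, and a change in translation after deflagellation stays open.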

How the results depend on the processing

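Totals without the 2 most abundant genes, thinning and the sphingolipid list without the sptl genes were chosen after the data were seen. Of 245 recomputed counts of calls and overlaps 190 stayed within 1.5 times, 47 fell and 8 rose further; of 516 list results 463 kept their side of the threshold, 42 lost and 11 gained a call; of 2063 results of single named genes 1862 kept it, 200 lost and 1 gained a call. Among called results no gene or camera list direction reversed (0), and unless stated the cause was not tested. Counts of calls have no direction, but with library totals their balance turned, in sptl-3 from 2237 higher and 3585 lower to 5124 and 1819 and for translational efficiency at 30 min from 143 and 26 to 108 and 279, and the medians of several lists changed sign. DESeq2 called 295, 429, 393 and 376 genes in the RNA-seq at 15, 30, 60 and 90 min and 454 between 30 and 90 min, and in the Ribo-seq 2110 at 15 min, 2088 at 60 min, 2384 at 90 min and 2190 between 30 and 90 min. Library totals gave 1156 RNA-seq calls at 90 min, and 257, 387, 831 and 1235 calls of translational efficiency at the 4 times; totals without the 2 most abundant genes gave 431 and 640 of the latter at 60 and 90 min. Ratios tested with limma gave 102, 84, 124 and 121 calls of translational efficiency. Fits on the compared groups alone called 2934 genes in sptl-1 and 1431 between sptl-2 and sptl-3. Thinned libraries, with fewer counts, called 750 in sptl-1 and 2808 between sptl-1 and sptl-2. With a minimum of 2-fold, which leaves fewer genes, the overlaps higher and lower were 34 and 58 for sptl-1 with sptl-2, 27 and 149 for sptl-1 with sptl-3, and 478 and 320 for sptl-2 with sptl-3.

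Without a filter the RNA-seq calls were 396 higher and 136 lower, 515 and 242, 430 and 190, and 392 and 214 at the 4 times, and those of translational efficiency 174 and 3, 183 and 6, 154 and 9, and 153 and 16. Without each library in turn, where the lone library is assumed to vary like the other groups, calls ran from 341 to 439, 518 to 669, 419 to 558 and 404 to 558 in the RNA-seq at the 4 times and from 525 to 667 between 30 and 90 min. In the Ribo-seq they ran from 2088 to 2870, 2584 to 3383, 1893 to 2781 and 2242 to 3139, and from 2516 to 2686 between 30 and 90 min. For translational efficiency they ran from 135 to 181, 130 to 177, 135 to 194 and 152 to 213. In the worm they ran from 275 to 509 in sptl-1, 790 to 2997 in sptl-2 and 3199 to 4965 in sptl-3, and from 1595 to 3607, 3488 to 5263 and 697 to 3120 for sptl-1 with sptl-2, sptl-1 with sptl-3 and sptl-2 with sptl-3. The libraries that moved a total of calls by over 1.5 times were RNA-seq non-treated replicate 2 (341, 518, 419 and 404) and 90 min replicate 1 (525), and Ribo-seq non-treated replicate 1 (2088, 2096 and 2242 at 15, 60 and 90 min) and 60 min replicate 2 (1893). In the worm they were wild-type replicates 1 and 2 (275 and 368 in sptl-1, 790 and 1258 in sptl-2, 3199 and 3572 in sptl-3), sptl-1 replicates 1 and 2 (509 and 387), sptl-2 replicate 2 (1650) and sptl-3 replicate 1 (3288). Between mutants they were sptl-1 replicate 2 (1595 and 3488), sptl-2 replicate 2 (2439), sptl-2 replicate 1 (950) and sptl-3 replicate 1 (3554 and 697).

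Samples with the same replicate number did not deviate together, with correlations of deviations from −0.05 to 0.10 in the RNA-seq, −0.05 to 0.11 in the Ribo-seq and −0.14 to 0.07 in the worm, and although the labels take the reference of the alga from the same culture, they do not say that a number marks a culture, so the numbers were not taken as pairs. With a replicate block the calls were 558, 785, 700 and 647 in the RNA-seq at the 4 times and 794 between 30 and 90 min, 3109, 3673, 3062 and 3546 in the Ribo-seq and 3367 between 30 and 90 min, and 164, 168, 181 and 205 for translational efficiency. In the worm they were 914, 2713 and 5462 for sptl-1, sptl-2 and sptl-3, and 3860, 5711 and 1964 between mutants. The block ended 13 calls of named genes and 0 of lists. Recovery of simulated 2-fold changes was lowest in the alga, at 10% of genes in the RNA-seq and 8% in translational efficiency. A gene without a call there was therefore not shown to be unchanged.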

Other observations

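The lists in this part and the shuffle of neighbouring pairs were chosen after the data were seen. Histone genes rose together in the sptl-3 mutant, 43 of 56 with 5 lower (50 adjusted over the list alone), with a median log2 change of 3.004, or 3.05 with RLE factors and 3.40 with library totals. For the histone list in sptl-3 camera gave adjusted p = 2.6e-34, fry adjusted p = 0.0125, and adjusted p = 0.192 with an estimated correlation. The falls were those of his-71 (−1.75), which encodes the replacement histone H3.3, his-37 (−1.29), his-35 (−1.14), his-41 (−0.82) and his-72 (−0.53), also a gene of H3.3. In the sptl-2 mutant 18 histone genes rose and 4 fell, with a median of 1.09, and for this list camera gave adjusted p = 4.0e-06, fry adjusted p = 0.139, and adjusted p = 0.562 with an estimated correlation. In the sptl-1 mutant edgeR called 0 of 56 and DESeq2 called 2, with 10 at an unadjusted edgeR p below 0.05 and a median of 0.22 (camera adjusted p = 0.124). The summed level of all histone genes moved far less, from 1544 ± 27.6 CPM in wild type to 1939 ± 146 in sptl-1, 1215 ± 305 in sptl-2 and 1795 ± 103.7 in sptl-3 (SD, n = 2), and the 5 genes that fell were the 5 most abundant histone genes in wild type.

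Of the large families of receptor and protein turnover genes, those called by camera against wild type did not pass fry. Of 607 serpentine receptor genes, which encode mostly chemosensory G protein-coupled receptors, 82 rose and 9 fell in sptl-3 (median 0.49, camera adjusted p = 8.3e-05; fry adjusted p = 0.0532; adjusted p = 0.367 with an estimated correlation). In sptl-2 41 of them rose and 3 fell (median 0.24, camera adjusted p = 0.0151; fry adjusted p = 0.194; adjusted p = 0.562 with an estimated correlation), and in sptl-1 1 rose and 5 fell (median −0.07, camera adjusted p = 0.904). Of 267 F-box, MATH and BTB genes, whose products serve in part as adaptors of ubiquitin ligases, 26 rose and 6 fell in sptl-2 (median 0.21, camera adjusted p = 0.0126; fry adjusted p = 0.0532; adjusted p = 0.367 with an estimated correlation). In sptl-1 1 rose and 14 fell (median −0.18, camera adjusted p = 0.0125; fry adjusted p = 0.0532; adjusted p = 0.367 with an estimated correlation), and in sptl-3 19 rose and 18 fell (median 0.10, camera adjusted p = 0.193). The direct difference between sptl-1 and sptl-2 had 6 genes of this list higher in sptl-1 and 57 lower (median −0.47, camera adjusted p = 4.0e-05; fry adjusted p = 0.0125; adjusted p = 0.192 with an estimated correlation). The summed level of neuropeptide and insulin genes was 14345 ± 180 CPM in wild type, 18010 ± 1110 in sptl-1, 9885 ± 666 in sptl-2 and 10037 ± 29.1 in sptl-3 (SD, n = 2), and that of intestine markers 23031 ± 858, 11367 ± 71.0, 14205 ± 2267 and 6939 ± 384 (SD, n = 2).

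In the alga it was tested whether genes whose footprints rose at 30 min lie next to each other in the genome more often than chance. Of 4442 adjacent pairs of tested genes 333 had both genes called higher, against a median of 262 and at most 305 in 1000 shuffles of the calls over the tested genes. Among the 4418 pairs that do not overlap the number was 330, against a median of 261 and at most 311. Neighbouring genes may therefore share part of their response, and reads that belong to both genes of an overlapping pair (24 pairs) do not account for the excess. The correlation of the log2 changes of neighbours was 0.083 across pairs, and gene order came from the reference assembly Chlamydomonas_reinhardtii_v5.5.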
